A study of Mus musculus with 9 samples.

How the data were processed

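The samples were 3 cyclin D1 knockout 3T3 lines, each infected with each of 3 retroviruses, and RNA was extracted 7 days after infection, per the labels. Per the labels' protocols, cells were grown with 10% serum, 5 µg of total RNA was reverse transcribed with an oligo-dT primer carrying a T7 promoter, and 15 µg of biotin-labelled cRNA was fragmented and hybridised to Affymetrix Mouse Genome 430 2.0 arrays. Priming at the poly(A) tail makes values depend on RNA length and on how far the labelled product reaches towards the 5' end. The deposited values are log2 expression values per probe set, made by the authors with RMA per the submitters' processing notes, which corrects background, normalizes quantiles across arrays and summarises probes. The software version is not given in the sources used here. The log2 scale was taken from the values, whose quartiles were nearly equal on all arrays. Quantile normalization removes any change that most genes share.

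The 64 Affymetrix control probe sets were left out of the tests and used to look at array quality, which left 45037. Genes were named through the platform annotation that was provided, matched to list symbols through RefSeq gene tables of GRCm38.p6. A gene's representative probe set was the one with the highest mean over all 9 arrays among those that name 1 gene. The 9160 probe sets without a gene in that annotation are unnamed here. Some genes of the fixed lists had no probe set under their name and are not analysed here, so 674 of 719 different list genes were measured.

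Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values of all 9 arrays, with the cell line as a fixed block, 4 residual degrees of freedom and Benjamini-Hochberg adjustment over 45037 probe sets, 2-sided, at 0.05. Differences are the first group named minus the second, with moderated standard errors. The line numbers pair the samples because each number is 1 cell line that received all viruses. Deviations from the group means correlated between arrays of a line with r from 0.168 to 0.831, and between arrays of different lines with r from -0.640 to 0.217. Deviations within a group cancel out by construction, which pushes correlations between different lines towards negative values. The ranges also overlap, so the contrast between them is no test of the pairing. The replicates of a group are different cell lines, so p-values rest on the spread of virus differences between lines, pooled over the viruses. With 1 array per line and virus, this spread holds a line's response, its infection and array noise together. A missed threshold therefore need not mean that the lines responded differently. No array was a copy of another, since the SD of the difference was at least 0.188 for each pair. Each cell line gave 1 array per virus, so no separate infections of a line were compared.

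The 33 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives, except those said to be chosen after seeing the data. Lists with at least 5 measured genes, 32 in number, were tested with camera at a preset correlation of 0.01 on 18193 representative probe sets, with adjustment over the lists, and also with an estimated correlation and with fry. The result of 1 of these lists is not reported here. Camera asks whether a list differs from the other genes, and fry whether its genes move, on balance, one way. Named genes were, per comparison, those passing and moving the same way in all lines (10 with the largest change in each direction), or where fewer than 5 passed in a direction, those and then the genes with the smallest p up to 5, said not to have passed, skipping genes named only by a clone or number; up to 4 members with the smallest p of each list that was called or held a passing member and up to 2 of others; the D-type cyclins, with all probe sets of Ccnd1; and Thbs1 and Cdkn1b. The third gene of this last part had no probe set under its name in the annotation used and is not analysed here. Members named because they passed adjusted over a list alone were chosen after their values were seen. For the lines they were the 10 passing genes with the largest range of line means, and 4 genes each of the sex marker, Hox and imprinted lists. Genes given from the fit with a term for 2 arrays followed the same rule in that fit, which was chosen after seeing the data.

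Shared GFP arrays were allowed for with 100 simulated data sets without virus effects, drawn with each probe set's residual SD, the same on all arrays. The procedure was tested on simulated data over 45037 probe sets with 66, 67 and 67 probe sets changed by 0.5, 1 and 2 per comparison. For D1a against GFP, 3.03% of probe sets changed by 0.5, 67.2% of those changed by 1 and 91.0% of those changed by 2 on the log2 scale were recovered, with 6 false calls among 114. For D1b against GFP the shares were 9.09%, 64.2% and 91.0%, with 4 false calls among 114. For D1b against D1a they were 6.06%, 56.7% and 82.1%, with 2 false calls among 99. These simulated data gave all arrays the same SD and drew probe sets independently. The shares and false calls thus need not hold for arrays of unequal precision or for correlated probe sets. Alternatives left out the block or made it random, filtered dim probe sets, recentred or renormalized arrays, used a trended and robust prior or array weights (gene by gene, since the default estimate did not converge), left out lines and single arrays, took 1 probe set per gene, and used only the 6 arrays of a comparison. Of 39 simulated lists without a change, 0 were called by camera, but their probe sets were drawn independently, so this does not test lists of correlated genes.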

Results

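Messenger RNA was measured on Affymetrix Mouse Genome 430 2.0 arrays in 9 samples of mouse fibroblasts that lack a functional cyclin D1 gene. The 3 cell lines, numbered 1, 7 and 12 in the labels, are 3T3 lines, which are fibroblasts immortalised by serial passage, and came from littermate knockout embryos of embryonic day 14. The labels give them as separate cell lines. Each line was infected with a murine stem cell retrovirus that carried cyclin D1a (the full-length form), cyclin D1b (an alternatively spliced form with a different carboxy terminus) or green fluorescent protein (GFP) as the control, and RNA was taken 7 days later. Each virus group thus held 3 arrays, 1 per line, and each line was compared with itself. On each array 45037 probe sets were tested, of which 34945 named 1 gene, 932 named several and 9160 are unnamed here, giving 18193 genes with a representative probe set. Array medians lay between 5.75 and 5.79 on the log2 scale. The precision is limited by the number of arrays.

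The arrays of D1b line 7 and GFP line 12 stood apart in their control probe sets. The Gapdh 5' control probe set read 13.26 in D1b line 7 and 13.64 in GFP line 12, against 9.55 to 10.54 on the other 7 arrays, and the control for the B1 repeat read 12.11 and 12.59 against 9.99 to 10.84. The difference between the 5' and 3' Gapdh control probe sets was -0.448 and -0.0827 on these arrays and -3.63 to -2.70 on the others. For Actb it was -0.901 and -0.750 against -2.04 to -1.53, and for Pcx -1.38 and -0.949 against -2.35 to -1.75. For Tfrc the D1b line 7 value of -2.72 lay within the other arrays' range of -3.19 to -2.58, and the GFP line 12 value was -2.45. No D1a array was among them, so D1a was compared with 1 such array in each of the GFP and D1b groups.

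**Figure D1:**
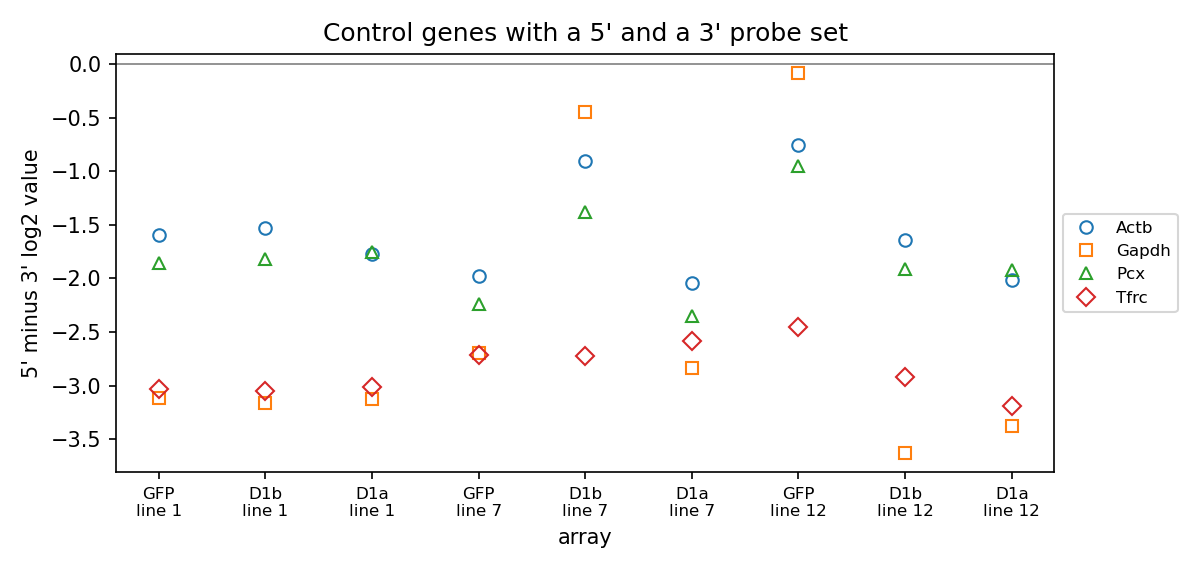
Difference between the 5' and the 3' control probe set of 4 control genes (log2 scale, vertical axis) on each of the 9 arrays (horizontal axis), 1 symbol per gene. In Actb, Gapdh and Pcx the D1b line 7 and GFP line 12 arrays lie above the other 7.

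The targeted gene was examined first. The 3 probe sets of Ccnd1, which encodes cyclin D1, gave D1a minus GFP differences of -0.00113 ± 0.105, 0.20 ± 0.161 and 0.0278 ± 0.105 (log2 ± SE), with adjusted p-values of 0.999, 0.672 and 0.940. The D1b minus GFP differences were -0.0811 ± 0.105, 0.0190 ± 0.161 and 0.11 ± 0.105. The D1b minus D1a differences were -0.0799 ± 0.105, -0.18 ± 0.161 and 0.0824 ± 0.105. None of these passed. The sign differed between lines in all but the D1b minus GFP difference of the brightest probe set, which was positive in each line. The probe sets are given from the dimmest to the brightest. Which part of the transcript these probe sets read, and whether the viral inserts contain it, is not given in the sources used here, so they check neither the knockout nor the level of either transgene.

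Among the other D-type cyclins, Ccnd2 had a mean log2 value of 13.13 ± 0.273 (SD, n = 3) with GFP, 12.67 ± 0.182 with D1b and 12.13 ± 0.209 with D1a, in this order within each of the 3 lines. The D1a minus GFP difference of its representative probe set was -0.996 ± 0.0913 (SE, adjusted p = 0.0557), the D1b minus GFP difference -0.45 ± 0.0913 (SE, adjusted p = 1.00) and the D1b minus D1a difference 0.54 ± 0.0913 (SE, adjusted p = 0.636). In D1a minus GFP, all 7 Ccnd2 probe sets were negative, between -1.64 and -0.976. In line 7, where the D1b array was one of those that stood apart, 2 of the 7 were higher with D1b than with GFP. The representative probe set of Ccnd3 gave -0.58 ± 0.0866 (SE, adjusted p = 0.0783) for D1a minus GFP, -0.16 ± 0.0866 (SE, adjusted p = 1.00) for D1b minus GFP and 0.41 ± 0.0866 (SE, adjusted p = 0.679) for D1b minus D1a. Its other probe sets differed by 0.0290 and -0.0819 between D1a and GFP. With all arrays weighted alike and no term for any array, no cyclin D difference passed the threshold of 0.05 over all probe sets. For D1a minus GFP, the representative probe set of Ccnd2 passed with a term for the D1b line 7 and GFP line 12 arrays (adjusted p = 0.00593) and without them (adjusted p = 0.0307), settings chosen after seeing the data. In planned settings adjusted over genes, the representatives of Ccnd2 and Ccnd3 passed for D1a minus GFP (adjusted p = 0.0268 and 0.0425), as did the mean of the Ccnd2 probe sets (-1.26, adjusted p = 0.0243) but not that of Ccnd3 (adjusted p = 0.208). The Ccnd3 mean includes the probe set that differed by 0.0290. It lay at 3.34 with D1a and 3.31 with GFP, below the lower quartile of probe set means (4.20). The one that differed by -0.0819 lay above it, at 7.34 and 7.42. The representative of Ccnd3 also passed with the term (adjusted p = 0.0197) and not without the arrays (adjusted p = 0.0599).

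**Figure D2:**
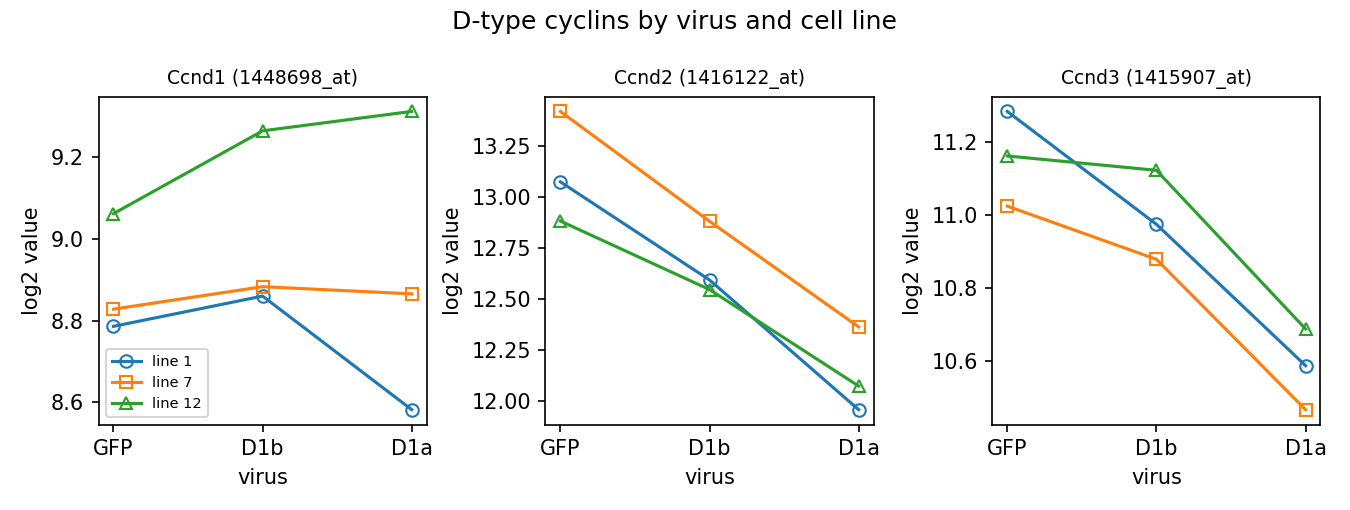
Log2 value (vertical axis) of the representative probe sets of Ccnd1, Ccnd2 and Ccnd3 by virus (horizontal axis), 1 symbol and line per cell line. Ccnd2 and Ccnd3 lie lowest with D1a in each line, and Ccnd1 shows no common order.

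The comparison of D1a with GFP addressed what full-length cyclin D1 changes in cells that lack it. Genes of DNA replication that are targets of E2F transcription factors were shifted upwards: 38 of the 39 measured members had a higher mean with D1a, the median log2 difference was 0.69 (0.64, 0.61 and 0.80 in lines 1, 7 and 12), and the list differed from the other genes with adjusted p = 3.99e-27 by camera at a preset correlation of 0.01 (adjusted p = 0.0785 with an estimated correlation). No member passed over all 45037 probe sets. With 1 representative probe set per gene, adjusted over 18193 genes, 12 passed, among them Lig1 (adjusted p = 0.0276) and Pola1 (adjusted p = 0.0330), and 31 passed adjusted over the list alone, all with higher values. Lig1, which encodes the DNA ligase that joins Okazaki fragments, was at 11.66 ± 0.194 with D1a and 10.84 ± 0.309 with GFP (SD, n = 3), a difference of 0.81 ± 0.0901 (SE, adjusted p = 0.0582). Mcm10, Pola1 (a subunit of DNA polymerase alpha) and Gins1 (a subunit of the replicative helicase) gave 0.92 ± 0.118 (SE, adjusted p = 0.0635), 0.97 ± 0.126 (SE, adjusted p = 0.0639) and 0.97 ± 0.125 (SE, adjusted p = 0.0651).

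The mitosis and G2/M list was also shifted upwards with D1a, with 34 of 34 members higher, a median of 0.42 and adjusted p = 3.09e-17 by camera (adjusted p = 0.128 with an estimated correlation). None passed over all probe sets, 2 passed over genes and 22 passed adjusted over the list alone, all higher. Spag5, a spindle protein, differed by 0.63 ± 0.0938 (SE, adjusted p = 0.0773), Espl1, which encodes separase, by 0.50 ± 0.0802 (SE, adjusted p = 0.0892), and Ccna2, which encodes cyclin A2, by 0.49 ± 0.0983 (SE, adjusted p = 0.124). All 22 measured DNA repair genes were higher, with a median of 0.50 and adjusted p = 1.68e-15 by camera (adjusted p = 0.106 with an estimated correlation), and 2 passed over genes, among them Rad51ap1 (adjusted p = 0.0268), and 19 adjusted over the list alone. Rad51ap1, a partner of the recombinase in homologous recombination, differed by 0.75 ± 0.0773 (SE, adjusted p = 0.0575), Rad54l by 0.69 ± 0.0864 (SE, adjusted p = 0.0614) and the mismatch repair gene Msh6 by 0.54 ± 0.0936 (SE, adjusted p = 0.0975). Smaller upward shifts were called for the interferon response list, with 22 of 30 members higher (median 0.26, adjusted p = 0.00539 by camera, adjusted p = 0.598 with an estimated correlation). Oxidative phosphorylation had 23 of 27 higher (median 0.11, adjusted p = 0.0287 by camera, adjusted p = 0.163 with an estimated correlation). Neither list had a member that passed, over probe sets, over genes or adjusted over the list alone, and both calls were lost without line 7 and with genes above the median signal alone. The interferon call was also lost without the replicate block (adjusted p = 0.111) and by fry (adjusted p = 0.426). Ifit1, an interferon-induced gene, differed by 1.34 ± 0.330 (SE, adjusted p = 0.186), with group SDs of 1.75 and 1.80. Ppargc1b, a coactivator of mitochondrial genes, differed by 0.55 ± 0.145 (SE, adjusted p = 0.205), whereas Ndufa4 was lower, at -0.43 ± 0.170 (SE, adjusted p = 0.382).

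Contractile and matrix genes were shifted downwards with D1a. All 10 smooth muscle markers had lower means, with a median of -0.69 (-0.62, -0.34 and -0.97 in lines 1, 7 and 12) and adjusted p = 7.44e-07 by camera (adjusted p = 0.141 with an estimated correlation), and 7 passed adjusted over the list alone. Lmod1, an actin nucleator of smooth muscle, differed by -0.77 ± 0.138 (SE, adjusted p = 0.101), Actg2, smooth muscle gamma-actin, by -1.03 ± 0.228 (SE, adjusted p = 0.152) and Myh11, smooth muscle myosin, by -0.69 ± 0.167 (SE, adjusted p = 0.180). Of 20 targets of SRF and YAP, 19 were lower, with a median of -0.28 and adjusted p = 4.54e-06 by camera (adjusted p = 0.0904 with an estimated correlation), and none passed adjusted over the list alone. This list shares Acta2, Tagln, Cnn1 and Actg2 with the smooth muscle markers, so the 2 lists are not separate evidence. Of 40 extracellular matrix genes 28 were lower, with a median of -0.20 and adjusted p = 8.26e-05 by camera (adjusted p = 0.126 with an estimated correlation), and 6 passed adjusted over the list alone. Tnc, which encodes tenascin C, was at 9.98 ± 0.545 with D1a and 11.14 ± 0.590 with GFP, a difference of -1.16 ± 0.147 (SE, adjusted p = 0.0614), and Thbs1, which encodes thrombospondin 1, differed by -0.68 ± 0.108 (SE, adjusted p = 0.0859). Matrix proteases and inhibitors had 17 of 22 lower (median -0.18, adjusted p = 1.99e-04 by camera, adjusted p = 0.141 with an estimated correlation). They included Adamts5, a proteoglycan-cleaving protease, at -0.63 ± 0.0966 (SE, adjusted p = 0.0783) and Timp3 at -0.64 ± 0.117 (SE, adjusted p = 0.106), and Adamts5, Timp3 and Mmp23 passed adjusted over the list alone. No member of these lists passed over all probe sets. Over genes, 0 smooth muscle markers, 0 SRF and YAP targets, 2 matrix genes and 1 of the proteases and inhibitors passed, all lower. Without the D1b line 7 and GFP line 12 arrays the smooth muscle median was -0.51 (adjusted p = 8.80e-06 by camera) and that of the matrix -0.13 (adjusted p = 3.49e-04).

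Downward shifts with D1a were also called for TGF-beta and BMP targets, with 15 of 19 lower (median -0.17, adjusted p = 0.00939 by camera, adjusted p = 0.141 with an estimated correlation). Skeletal muscle markers had 15 of 22 lower (median -0.10, adjusted p = 0.00752 by camera, adjusted p = 0.305 with an estimated correlation). Growth factor immediate early and ERK feedback genes had 17 of 26 lower (median -0.13, adjusted p = 0.0214 by camera, adjusted p = 0.594 with an estimated correlation). The ligand gene Tgfb2 differed by -0.81 ± 0.108 (SE, adjusted p = 0.0663) and Tgfb3 by -0.74 ± 0.112 (SE, adjusted p = 0.0773). Tnni1, a troponin of slow muscle, differed by -0.72 ± 0.0946 (SE, adjusted p = 0.0654), and Dusp1, a phosphatase of MAP kinases, by -0.90 ± 0.108 (SE, adjusted p = 0.0604). Adjusted over the list alone, Tgfb2 and Tgfb3 of the TGF-beta and BMP list passed, Tnni1, Acta1 and Tnnt1 of the skeletal muscle list and Dusp1 of the immediate early list, all lower, and none over all probe sets. Over genes, 2, 2 and 1 members of these 3 lists passed, all lower, among them Dusp1 (adjusted p = 0.0309). The immediate early median was -0.24 without the D1b line 7 and GFP line 12 arrays, and its call was lost without line 1 or line 7 and with genes above the median signal alone. The skeletal muscle call was lost without line 12 and without the replicate block (adjusted p = 0.0822). By fry the immediate early, TGF-beta and BMP and skeletal muscle calls were all lost (adjusted p = 0.384, 0.0635 and 0.0921). Without the D1b line 7 and GFP line 12 arrays the skeletal muscle list was not called (median 0.0153, adjusted p = 0.126), and with a term for them neither it nor the TGF-beta and BMP list was (adjusted p = 0.169 and 0.0865). A further 19 lists had adjusted p-values by camera between 0.0855 and 0.910. Their medians were -0.0776 for glycolysis, -0.12 for NF-kB and inflammatory genes, -0.11 for endoplasmic reticulum stress and amino acid response, -0.0515 for imprinted genes, 0.12 for p53 targets and -0.0241 for adipocyte and lipid storage. They were -0.00705 for epithelial markers, 0.0806 for G1 cyclins, CDKs, inhibitors and pocket proteins, 0.0902 for NRF2 targets, -0.00418 for neural and glial markers, -0.0487 for endothelial markers and 0.0331 for Notch pathway. In the others they were 0.0560 for sterol synthesis, 0.0159 for Hox genes, -0.00269 for fibroblast identity, -0.0237 for Wnt pathway, 0.0369 for macrophage and haematopoietic markers, -0.0459 for cartilage and bone markers and 0.11 for small RNA processing. For the Wnt list and for cartilage and bone the median and the mean differed in sign.

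No single gene passed over all probe sets in this comparison. With limma and the cell line as a block, 0 of 45037 probe sets had an adjusted p under 0.05, with a smallest adjusted p of 0.0557, while 5414 had an unadjusted p under 0.05 (3057 higher, 2357 lower) where 2252 would be expected by chance. This count was 3248 to 8150 when single arrays were left out and 2483, 6534 and 4000 without lines 1, 7 and 12, so that without line 1 it lay near the 2252. The genes with the smallest p, none of which passed over all probe sets, were higher for Rbmx, an RNA-binding protein (0.97 ± 0.0905, adjusted p = 0.0557), Rad51ap1, Recql4, a DNA helicase (0.79 ± 0.0820, adjusted p = 0.0575), Nemp1 (0.85 ± 0.0899, adjusted p = 0.0575) and Lig1. They were lower for Selp, which encodes P-selectin (-1.30 ± 0.0922, adjusted p = 0.0557), Bdh1, a ketone body enzyme (-1.14 ± 0.0865, adjusted p = 0.0557), Mgll, which encodes monoglyceride lipase (-1.71 ± 0.151, adjusted p = 0.0557), Dmpk (-1.04 ± 0.0936, adjusted p = 0.0557) and Ccnd2. Cdkn1b, which encodes the inhibitor p27, differed by 0.44 ± 0.164 (SE, adjusted p = 0.360).

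The count differed between settings. Without GFP line 12 alone 41 probe sets passed (3 higher, 38 lower). Without GFP line 7 alone 1 passed, and with array weights 2199. With 1 representative probe set per gene, 160 of 18193 genes passed (58 higher, 102 lower), among them Rbmx, Rad51ap1, Recql4, Nemp1, Selp, Bdh1, Mgll and Dmpk (each at adjusted p = 0.0268). With the mean of each gene's probe sets, a setting planned for single genes and applied to the count after seeing the data, 172 passed (74 higher, 98 lower), including 19 of the 57 examined differences, but not Rad51ap1 or Selp (adjusted p = 0.0781 and 0.0645). By contrast, 0 of the 22518 probe sets above the median signal and 0 of the 33777 above the lower quartile passed (3494 and 4552 at an unadjusted p under 0.05). With a term for the D1b line 7 and GFP line 12 arrays, chosen after seeing the data and with the line block kept, 1468 probe sets passed (590 higher, 878 lower). With both arrays left out 154 passed (33 higher, 121 lower), of which 149 also passed with the term, as did 1168 of the 2199 called with array weights. In the fit with the term, 31 of the 39 E2F and DNA replication genes passed over all probe sets, 8 of the 34 mitosis genes and 10 of the 22 DNA repair genes, all higher, and 2 of the 10 smooth muscle markers, both lower. Without the 2 arrays 7, 0, 1 and 0 members of these lists passed. Genes that passed in the fit with the term and moved the same way in all 3 lines included Olfml3 at 1.46 ± 0.200 (SE, adjusted p = 0.0170), E2f8, an E2F family member, at 1.17 ± 0.105 (SE, adjusted p = 0.00671), and Dscc1, a replication factor, at 1.15 ± 0.0953 (SE, adjusted p = 0.00596). Among the lower ones were Aldh1a7 at -2.50 ± 0.205 (SE, adjusted p = 0.00593), Scel at -2.04 ± 0.112 (SE, adjusted p = 0.00255), the neuropeptide gene Vip at -1.96 ± 0.170 (SE, adjusted p = 0.00639) and Aldh1a1, a retinal dehydrogenase, at -1.75 ± 0.192 (SE, adjusted p = 0.00960). Without both arrays Olfml3 did not pass (adjusted p = 0.0575). Adjusted over genes without the term, the representatives of Aldh1a7 and Aldh1a1 did not pass (adjusted p = 0.0561 and 0.0743). Scel passed with its representative (adjusted p = 0.0347) but not with the mean of its probe sets (-0.79, adjusted p = 0.0741). E2f8 and Dscc1 passed both ways. So did Olfml3 and Vip, but their gene means equal their representative values, so the mean is no second check for them.

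**Figure D3:**
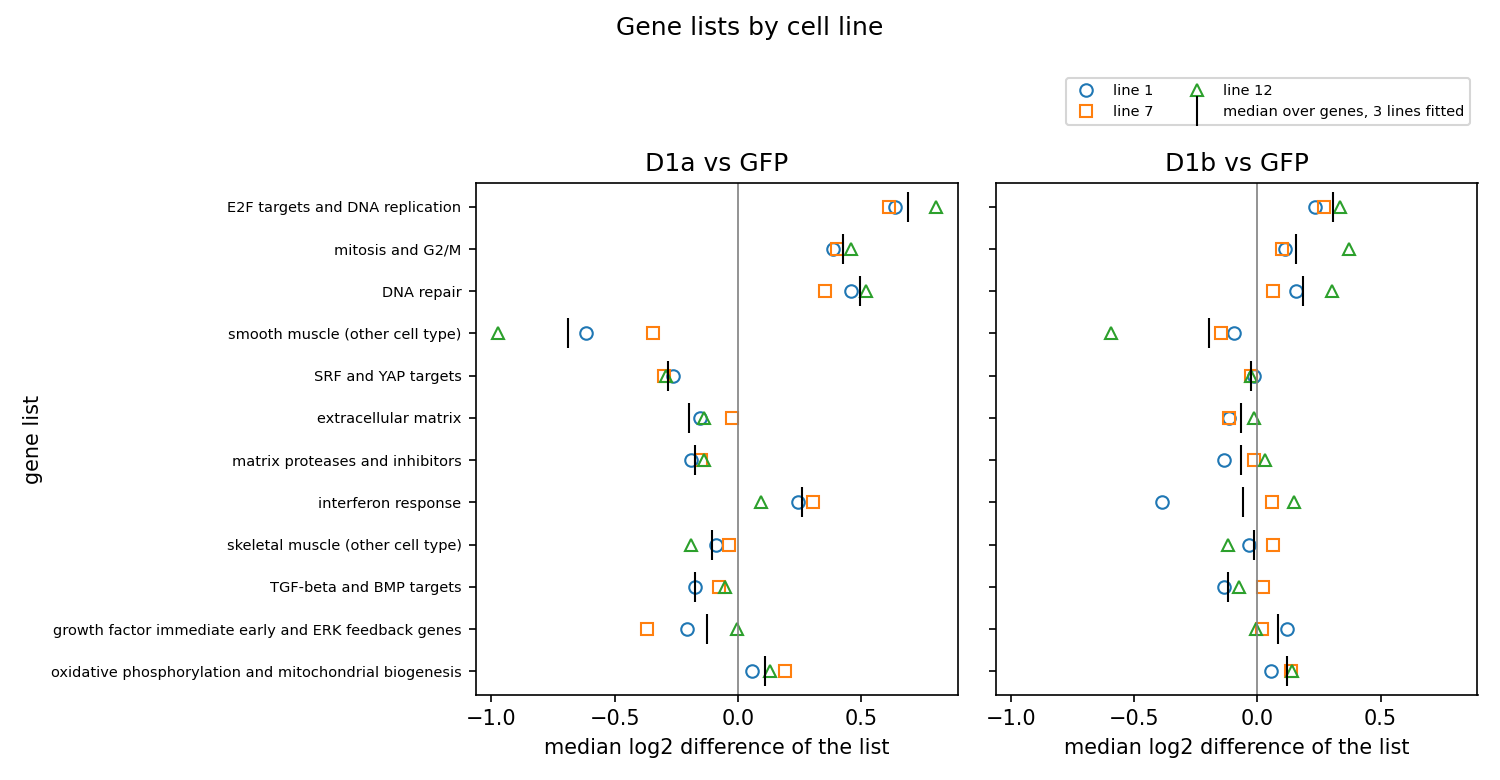
Median log2 difference (horizontal axes) of each gene list called in D1a against GFP or D1b against GFP (vertical axis), for D1a minus GFP (left) and D1b minus GFP (right). Symbols are the 3 cell lines, each 1 array against 1 array, and the bar is the median of the fitted differences. The E2F and DNA replication list lies above 0 in each line in both panels.

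The comparison of D1b with GFP asked the same of the spliced form. The E2F and DNA replication list was again shifted upwards, with 38 of 39 members higher and a median of 0.31 (0.24, 0.27 and 0.33 in lines 1, 7 and 12; adjusted p = 1.38e-18 by camera, adjusted p = 0.158 with an estimated correlation). No member passed over all genes and 0 passed adjusted over the list alone. Gins2 differed by 0.46 ± 0.124 (SE), Mcm2, a helicase subunit, by 0.39 ± 0.109, and Lig1 by 0.30 ± 0.0901, each with an adjusted p of 1 in the fit over all probe sets. The mitosis list had 34 of 34 members higher (median 0.16, adjusted p = 1.41e-09 by camera, adjusted p = 0.359 with an estimated correlation), and DNA repair had 18 of 22 higher (median 0.18, adjusted p = 1.46e-07 by camera, adjusted p = 0.359 with an estimated correlation). Ccna2 differed by 0.30 ± 0.0983 and Msh6 by 0.39 ± 0.0936. Oxidative phosphorylation was shifted upwards with 23 of 27 higher (median 0.12, adjusted p = 0.00701 by camera, adjusted p = 0.323 with an estimated correlation), with Mrpl12, a mitochondrial ribosomal protein, at 0.45 ± 0.138. In none of these lists did a member pass adjusted over the list alone.

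Smooth muscle markers were shifted downwards with D1b, with 8 of 10 lower (median -0.20, adjusted p = 0.0130 by camera, adjusted p = 0.627 with an estimated correlation). So were extracellular matrix genes, with 29 of 40 lower (median -0.0657, adjusted p = 0.0227 by camera, adjusted p = 0.359 with an estimated correlation). No member of either passed, over all genes or adjusted over the list alone. Myh11 differed by -0.31 ± 0.167 and Tnc by -0.52 ± 0.147. Without the D1b line 7 and GFP line 12 arrays, neither was called (adjusted p = 0.540 and 0.208), nor was oxidative phosphorylation (adjusted p = 0.0981). With both left out, only line 1 held a D1b and a GFP array. The difference then rested on that line and on indirect comparison through D1a. The smooth muscle call was also lost with a term for the 2 arrays (adjusted p = 0.0535), with genes above the median signal alone (adjusted p = 0.172) and without line 12. The term left the median at -0.20, since the GFP and D1b groups each held 1 of the arrays. Its loss of the call is thus no second check of the shift. Without the replicate block both the smooth muscle and the matrix call were lost (adjusted p = 0.0678 and 0.0965). The matrix call was also lost without line 1 or line 12, and that of oxidative phosphorylation without line 7 or line 12. The median and the mean, or either and the test, differed in sign for the fibroblast identity, Wnt, neural and glial, glycolysis and p53 lists. By the rotation test fry, 0 lists were called for D1b against GFP. A further 25 lists had adjusted p-values between 0.210 and 0.973. Of all probe sets, 0 passed in limma, the smallest adjusted p was 1, and 1827 had an unadjusted p under 0.05, fewer than the 2252 expected by chance. That count was 1361 to 4408 when single arrays were left out, highest without GFP line 12, and 926, 2147 and 3354 without lines 1, 7 and 12, thus on both sides of chance. The smallest p among higher genes belonged to Rbmx at 0.53 ± 0.0905, Aunip at 0.57 ± 0.104, the histone acetyltransferase gene Hat1 at 0.44 ± 0.0834, Atp23 at 0.45 ± 0.0914 and Usp14 at 0.38 ± 0.0800. Among lower genes it belonged to Mamdc2 at -0.80 ± 0.103, Selp at -0.64 ± 0.0922, Lancl3 at -0.91 ± 0.135, Myom1 at -1.01 ± 0.156 and Dner at -0.72 ± 0.115, none of which passed. Across all settings tried, including array weights and the term for the 2 arrays, 0 probe sets passed. Thbs1 gave -0.0554 ± 0.108 and Cdkn1b 0.19 ± 0.164.

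The direct comparison of D1b with D1a tested whether the forms differ, and its differences use no GFP array. The D1b line 7 array is one of those that stood apart. The E2F and DNA replication list was lower with D1b than with D1a, with 34 of 39 members lower and a median of -0.36 (-0.40, -0.27 and -0.38 in lines 1, 7 and 12; adjusted p = 7.84e-17 by camera, adjusted p = 0.0947 with an estimated correlation). Adjusted over the list alone, 20 members passed, all lower, and none over all genes. Lig1 differed by -0.52 ± 0.0901 (SE, adjusted p = 0.636), Gins1 by -0.69 ± 0.125 (SE, adjusted p = 0.636) and Pola1 by -0.67 ± 0.126 (SE, adjusted p = 0.636). DNA repair had 22 of 22 members lower (median -0.27, adjusted p = 2.05e-11 by camera, adjusted p = 0.177 with an estimated correlation), with 7 passing adjusted over the list alone, and mitosis had 30 of 34 lower (median -0.26, adjusted p = 3.75e-10 by camera, adjusted p = 0.211 with an estimated correlation), with 0 passing. Rad51ap1 differed by -0.48 ± 0.0773 (SE, adjusted p = 0.636) and Mki67, a proliferation marker, by -0.50 ± 0.120 (SE, adjusted p = 0.712). The interferon list had 26 of 30 members lower and 0 passing adjusted over the list alone (median -0.23, adjusted p = 1.52e-06 by camera, adjusted p = 0.422 with an estimated correlation). It was not lower in line 12, with line medians of -0.58, -0.36 and 0.0657 in lines 1, 7 and 12. Ifit1 differed by -1.30 ± 0.330 (SE, adjusted p = 0.724).

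Higher with D1b than with D1a were the SRF and YAP targets, with 19 of 20 members higher (median 0.28, adjusted p = 2.77e-07 by camera, adjusted p = 0.0947 with an estimated correlation). So were smooth muscle markers with 9 of 10 higher (median 0.50, adjusted p = 2.31e-05 by camera, adjusted p = 0.211 with an estimated correlation), and immediate early and ERK feedback genes with 21 of 26 higher (median 0.32, adjusted p = 1.24e-05 by camera, adjusted p = 0.322 with an estimated correlation). The SRF and YAP and the smooth muscle lists share Acta2, Tagln, Cnn1 and Actg2. The immediate early median was 0.31, 0.58 and -0.0617 in lines 1, 7 and 12, 0.20 with the term for the 2 arrays and 0.18 without them, still called in both. Adjusted over the list alone, Dusp1 of the immediate early list passed and none of the other 2 lists, and none passed over all genes. Fhl2 differed by 0.63 ± 0.155 (SE, adjusted p = 0.712), the stress-responsive Ankrd1 by 0.70 ± 0.195 (SE, adjusted p = 0.771), Lmod1 by 0.54 ± 0.138 (SE, adjusted p = 0.732) and Dusp1 by 0.83 ± 0.108 (SE, adjusted p = 0.636). Extracellular matrix genes had 29 of 40 higher, of which Thbs1 passed adjusted over the list alone (median 0.0941, adjusted p = 0.00220 by camera, adjusted p = 0.211 with an estimated correlation). Matrix proteases and inhibitors had 17 of 22 higher, of which Adamts5 and Timp1 passed adjusted over the list alone (median 0.14, adjusted p = 9.05e-04 by camera, adjusted p = 0.211 with an estimated correlation). Thbs1 differed by 0.62 ± 0.108 (SE, adjusted p = 0.636) and Adamts5 by 0.53 ± 0.0966 (SE, adjusted p = 0.636). The matrix median was 0.0540, -0.00408 and 0.20 in lines 1, 7 and 12, and 0.0519 with the term, still called. Calls were also made for glycolysis, with 12 of 17 higher (median 0.15, adjusted p = 0.0185 by camera, adjusted p = 0.322 with an estimated correlation), and for TGF-beta and BMP targets, with 14 of 19 higher (median 0.18, adjusted p = 0.0323 by camera, adjusted p = 0.211 with an estimated correlation). Skeletal muscle markers had 14 of 22 higher (median 0.0400, adjusted p = 0.0138 by camera, adjusted p = 0.322 with an estimated correlation). Adjusted over the list alone, 0 glycolysis genes, Tgfb3 and Inhba of the TGF-beta and BMP list and Tnni1 of the skeletal muscle list passed. The TGF-beta and BMP median was -0.00767 in line 12. All 3 calls were lost with the term for the 2 arrays, with adjusted p-values of 0.194, 0.156 and 0.330. All 3 were also lost without the 2 arrays (adjusted p = 0.174, 0.358 and 0.152) and without line 7. Without the replicate block the TGF-beta and BMP call and the skeletal muscle call were lost (adjusted p = 0.107 and 0.197), and the former also after quantile normalization (adjusted p = 0.0620) and with genes above the median signal alone. Calls were also lost for glycolysis and the extracellular matrix without line 12, and for interferon without line 1. By fry 10 of the 12 calls were lost, among them DNA repair (adjusted p = 0.0579), mitosis (adjusted p = 0.0974) and smooth muscle (adjusted p = 0.162). Only the E2F and DNA replication list and the SRF and YAP list stayed called by fry (adjusted p = 0.0217 each). A further 19 lists had adjusted p-values by camera between 0.104 and 0.930. Among these the median and the mean, or either and the test, differed in sign for macrophage, epithelial, cartilage and bone, Notch, adipocyte, fibroblast identity, G1 cyclin and sterol synthesis lists.

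Of all probe sets, 0 passed for D1b against D1a in limma (smallest adjusted p = 0.636), and 2763 had an unadjusted p under 0.05 against 2252 expected. That count was 1531 to 4699 when single arrays were left out and 1075, 1768 and 3147 without lines 1, 7 and 12, so an excess over chance depended on single arrays. The higher genes with the smallest p were Bdh1 at 0.77 ± 0.0865, Serpinb9b at 1.20 ± 0.151, Dusp1, Selp at 0.66 ± 0.0922 and Mgll at 0.999 ± 0.151. The lower ones were E2f8 at -1.04 ± 0.149, Rad51ap1, Pcdhb7 at -0.70 ± 0.117, Recql4 at -0.49 ± 0.0820 and Lig1. None of them passed. Cdkn1b gave -0.25 ± 0.164 (SE, adjusted p = 0.852).

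A moderated F test of any difference among the 3 viruses called 0 probe sets, with 3656 at an unadjusted p under 0.05 (2072 to 5336 when single arrays were left out, 1380 without line 1). It called 332 with the term for the 2 arrays and 744 with array weights. The D1a minus GFP and D1b minus GFP differences correlated across probe sets with a Pearson r of 0.633, where 100 simulated data sets with no virus effect and the same shared GFP arrays gave a mean r of 0.50 and a highest r of 0.522. Probe sets are not independent replicates. The covariance was 0.0242 against a simulated 0.0175, a difference of 0.00667. The same sign was found in 70.7% of probe sets against a simulated 66.7%. At an unadjusted p under 0.05, 534 probe sets were higher in both comparisons against 65.5 for independent lists (3057 times 965 over 45037), and 586 were lower in both against 45.1. The simulated data gave means of 328 and 329 (highest 368 and 366), from 1183 higher with D1a and 1187 with D1b, so the shared GFP arrays alone gave overlaps far above those for independent lists. The simulated probe sets were drawn independently of one another, unlike measured ones, so their spread is no bound on chance. The simulation also gave all arrays the same SD. The estimated array weights, where a low weight marks a noisier array, were 0.187 and 0.352 for GFP lines 12 and 7. They were 3.58 for GFP line 1, 1.26 to 2.06 for D1a and 0.298 to 2.79 for D1b. Noisier shared GFP arrays would raise r and the overlaps without any virus effect, so whether the 2 forms share effects stays open. With 3 GFP arrays the controls could not be split into groups of at least 2.

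The 3 cell lines differed from one another in 4354 of 45037 probe sets at an adjusted p under 0.05 (limma F test with the virus as the other factor). Line 12 expressed the Y-linked genes Eif2s3y, at 9.35 ± 0.449 (SD, n = 3) against 2.70 ± 0.0518 and 2.45 ± 0.0731 in lines 1 and 7, Kdm5d (7.27 ± 0.155 against 2.98 ± 0.0909 and 2.68 ± 0.0867) and Uty (6.17 ± 0.163 against 3.57 ± 0.111 and 3.32 ± 0.131). Xist, the RNA of the inactive X chromosome, was at 12.02 ± 0.193 and 11.83 ± 0.162 in lines 1 and 7 and at 5.29 ± 0.246 in line 12. The largest range among genes that passed was that of Pcolce2, a procollagen processing enhancer, at 11.36 ± 0.277 in line 1, 4.11 ± 0.2996 in line 7 and 6.59 ± 0.423 in line 12. Lrrn4, Gpm6a, Tex11 and Tm4sf1 were highest in line 7, with ranges of 6.53, 5.87, 5.77 and 5.63. Plac8 was lowest in line 12 (range 6.47) and Rpgrip1 lowest in line 7 (range 5.80). The imprinted growth factor gene Igf2 was at 11.79 ± 0.504 in line 7 against 6.34 ± 0.394 and 7.89 ± 0.801, and Nnat ranged over 2.50, whereas the ranges of Cdkn1c (1.66) and Dlk1 (1.64) did not pass. Of 28 Hox genes, 5 differed between lines, among them Hoxd8, Hoxb3, Hoxb5 and Hoxb9, with ranges of 1.97, 1.16, 1.09 and 1.04. The extracellular matrix list differed in 19 of 40 members. The X and Y chromosome list had 4 measured genes, too few for the list test, and all 4 differed between lines. With the term for the 2 arrays the count of probe sets that differed between lines was 11445, and without both arrays 7968. Leaving out single arrays gave 1310 to 6417, with 1310, 1613 and 1967 without D1b, GFP or D1a line 1.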

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

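The tests of exchanged labels, of the E2F and DNA replication list without 2 arrays, of the shared GFP arrays and of the transgene level were chosen only after the results were seen. The following results had cell lines that moved in opposite directions, each line being 1 array against 1 array, and the differences between lines were not tested. Of 30 list calls, 4 were of this kind, all for D1b minus D1a. The gap between the highest and lowest line median was 0.643 for the interferon response (lines 1, 7 and 12 at -0.58, -0.36 and 0.0657), 0.638 for immediate early and ERK feedback genes (0.31, 0.58 and -0.0617), 0.206 for the extracellular matrix (0.0540, -0.00408 and 0.20) and 0.223 for TGF-beta and BMP targets (0.11, 0.22 and -0.00767).

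Among named genes, 13 of 161 values were of this kind, given here as the gap between the highest and lowest line difference. For D1a minus GFP it was 0.308, 0.696 and 0.453 for the dimmest, middle and brightest Ccnd1 probe set and 0.915 for Ndufa4. For D1b minus GFP it was 0.377 and 0.729 for the dimmest and middle Ccnd1 probe set, 0.910 for Cdkn1b and 0.379 for Thbs1. For D1b minus D1a it was 0.333, 0.458 and 0.325 for the dimmest, middle and brightest Ccnd1 probe set, 0.609 for Cdkn1b and 0.786 for Ier3.

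The arrays of D1b line 7 and GFP line 12 stood apart from the other 7 in their control probe sets. An exchange of their labels is argued against by Xist, which was 6.42 higher in the array labelled D1b line 7, as the lines' sex markers require. A difference in RNA length or labelling predicts that probe sets of one gene, which lie at different places in its transcript, move apart in the same way in both arrays. Over 9010 genes, the gap between a gene's brightest and second brightest probe set, as a deviation from the other arrays of the line, correlated between these 2 arrays with r = 0.737, against -0.220 to 0.272 over 18 pairs that include an array of line 1 and -0.692 to 0.542 over the 8 other pairs of lines 7 and 12, whose deviations are partly taken from these arrays, so a technical difference in RNA or labelling is a candidate explanation. The 2 arrays share neither virus nor line, so the design names no biological explanation, and none was tested.

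These arrays are argued against as the whole source of the upward shift of the E2F and DNA replication list with D1a, since without both, its median was 0.643 against 0.689 with all arrays, and it stayed called at the preset correlation, although with all arrays an estimated correlation ended the call (adjusted p = 0.0785). The list with D1b lay between GFP and D1a, and the shared GFP arrays stay open for its part above GFP, since the D1b minus D1a median of -0.364 uses no GFP array and gives no measure of them. A lower level of the D1b transgene stays open, since the brightest Ccnd1 probe set differed by 0.0824 between D1b and D1a but did not differ detectably from GFP with either virus, and so it gives no measure of either transgene. A difference in activity between the forms, which the design names, also stays open, and these data do not separate it from dose.

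Other splits of the arrays, with the line block kept, were counted at an unadjusted p under 0.05. The 6 arrays of a comparison make 10 splits, too few for a share under 0.05. For D1a against GFP 2 of 10 splits gave as many probe sets as the real 5414, and the highest other gave 7994; for D1b against GFP 5 of 10 reached 1827, with 7508 as the highest other; for D1b against D1a 2 of 10 reached 2763, with 7088 as the highest other. For called lists, 1 of 10 reached the 12 for D1a against GFP (highest other 9), 2 of 10 reached the 6 for D1b against GFP (highest other 7) and 1 of 10 reached the 12 for D1b against D1a (highest other 9), so camera at the preset correlation calls several lists in splits that mix the viruses. Among the 4 splits that part all 3 lines as the real one does, the highest others were 1603, 7508 and 634 probe sets; the 7508 came from a split that puts D1b line 7 and GFP line 12 on one side, as does another with 6115. The other 6 splits keep both arrays of a line together for 2 lines and contrast only the remaining line, which was line 12 for the 7994 and line 7 for the 7088, each with an array that stood apart. With a term for these arrays the real comparisons gave 8548, 4977 and 4301. For the F test, 32 of 92 drawn splits that could be fitted, of 100 drawn from 280, reached the real 3656 (highest other 9307), as did 10 of the 36 splits with 1 array of each line per group (highest other 8756), so chance is not excluded for that count. Other splits with several times the real count, as for D1b against GFP, point to a structure of the samples.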

How the results depend on the processing

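The term for the D1b line 7 and GFP line 12 arrays, leaving both out, and the count over gene means were chosen after seeing the data. The other settings were planned. With both arrays left out, lines 1 and 7 paired D1a with GFP, lines 1 and 12 paired D1b with D1a, and only line 1 paired D1b with GFP. For D1a against GFP the count of 0 became 160 with 1 representative probe set per gene, 172 with the mean of each gene's probe sets, 2199 with array weights estimated gene by gene (the default estimate did not converge), 1468 with the term for the 2 arrays, 154 without them and 358 at a threshold of 0.10. The first 2 of these change both the number of tests and the probe sets tested, and testing only 22518 or 33777 brighter probe sets gave 0 (3494 and 4552 at an unadjusted p under 0.05). Leaving out arrays or lines gave 0 to 41, with 41 without GFP line 12 and 1 without GFP line 7 (2483 to 8150 at an unadjusted p under 0.05). For any difference among viruses the 0 became 744 with array weights and 332 with the term. Without the replicate block, that is unpaired, D1a against GFP, D1b against GFP and D1b against D1a called 0, 0 and 0 probe sets by limma (2734, 653 and 1078 at an unadjusted p under 0.05), and with the block as a random effect also 0. With the block the count was 0 as well, so no call could be lost. The smallest adjusted p for D1a against GFP was 0.0557 with the block and 0.445 without it. The count with 1 representative probe set per gene was not repeated without the block. For D1b against GFP and D1b against D1a all settings gave 0. At an unadjusted p under 0.05 they had 1827 and 2763, 881 and 5468 with only the 6 arrays of the comparison, and 7549 and 6494 with array weights. Differences between lines became 11445 with the term and 7968 without the 2 arrays, and 1310 to 6417 when single arrays were left out. They fell to 1310, 1613 and 1967 without D1b, GFP or D1a line 1, to 2140 without D1a line 7 and to 1917 without D1a line 12, and were 6417 without GFP line 12. The cause was not tested.

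Of 32 lists, 12, 6 and 12 were called for D1a against GFP, D1b against GFP and D1b against D1a. With an estimated correlation 0, 0 and 0 were called, and with fry 8, 0 and 2. Leaving out a line gave 10 to 14, 5 to 8 and 9 to 11. Without the replicate block (unpaired) 12, 4 and 10 were called, with the term 11, 5 and 11, and without the 2 arrays 13, 4 and 10. With genes above the median signal alone, 8 of 27 lists were called for D1a against GFP. For the E2F, mitosis, DNA repair, SRF and YAP, smooth muscle, matrix protease and extracellular matrix lists with D1a against GFP, the call was lost only with an estimated correlation. The test kept its direction in all of them. The skeletal muscle median turned to 0.0153 for D1a against GFP without the 2 arrays, and to -0.00548 for D1b against D1a. Of 358 list values under alternatives, 91 lost the call. The correlation of the D1a and D1b differences across probe sets, 0.633, became 0.642 above the median signal, 0.720 with the term, 0.726 without the 2 arrays, and 0.541 to 0.836 without a line. The design alone, with no virus effect and independent errors of equal size on all arrays, gives 0.466 with the term, 0.598 without the 2 arrays and 0.50 otherwise. These values thus have no common baseline, and noisier GFP arrays would raise it. Dim probe sets limit precision where the signal is near background.

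No difference with a reversed sign passed in the setting that reversed it. For D1a minus GFP, the dimmest Ccnd1 probe set ranged over -0.0809 to 0.0733 without a line, and was 0.0146 after quantile normalization, 0.0404 with the term and 0.0383 without the 2 arrays. The brightest Ccnd1 probe set ranged over -0.0830 to 0.143 without a line, and was -0.0156 with the term and -0.0478 without the arrays. For D1b minus GFP, without a line, the dimmest Ccnd1 probe set ranged over -0.174 to 0.0142, the middle one over -0.185 to 0.179, Cdkn1b over -0.0577 to 0.397 and Thbs1 over -0.177 to 0.0122, the sign turning without line 12. Without the 2 arrays the middle Ccnd1 probe set was -0.0601 and Actg2 0.0395, against -0.40 with all arrays and -0.511 to -0.210 without a line. For D1b minus D1a, without a line, the dimmest Ccnd1 probe set ranged over -0.156 to 0.0101 and the brightest over -0.0150 to 0.147.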

Other observations

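The G1 cyclins, CDKs, inhibitors and pocket proteins moved both ways with D1a, with 15 of 24 members higher and 9 lower, a median of 0.0806 and adjusted p = 0.555 by camera; adjusted over the list alone, Cdkn2c, Cdkn1a and Rbl1 were higher and Ccnd2, Ccnd3 and Cdk6 lower. Fibroblast identity genes did likewise, with Ptn, Tcf4 and Prrx1 higher and Thy1, S100a4 and Cd44 lower adjusted over the list alone and a median of -0.00269. Adjusted over genes, 0 members of the G1 list passed higher and 2 lower by representative probe set, and 1 and 1 by gene mean. For fibroblast identity these counts were 1 higher and 1 lower by representative probe set, and 0 and 1 by gene mean. Sterol synthesis with D1b was at a median of 0.0328 with all arrays (adjusted p = 0.788 by camera) and at 0.19 without the D1b line 7 and GFP line 12 arrays (adjusted p = 2.84e-04). With a term for them the list was not called (adjusted p = 0.792). The GFP and D1b groups each hold 1 of the arrays, so the term cannot change a D1b minus GFP difference. Its median of 0.0328 is therefore no second check. Leaving the arrays out kept both a D1b and a GFP array in line 1 only. Both settings were chosen after seeing the data, and with an estimated correlation the list with all arrays was at adjusted p = 0.965.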
